A study of Homo sapiens with 5 samples.

How the data were processed

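Mature miRNAs were measured in Caco-2, a human colorectal adenocarcinoma cell line of epithelial type, on 5 single-colour arrays: 1 of untreated cells and 1 each of cells given TNFα, IL1α, IL1β or IL6. Total RNA was labelled with Hy5 and hybridised to 3D-Gene human miRNA chips, per the labels' protocols and the file headers. Each array carried 3136 spots, of which 1719 were miRNA probes with 1 spot each and 1248 were blanks. The deposited scanner files give the intensity of each spot and of its surroundings at 635 nm, with no normalization or background subtraction recorded, per the file headers. The deposited value table gives the authors' processed intensities on a linear scale. Its columns have medians of 24.9865 for the control and 25 for the 4 cytokine arrays. For bright miRNAs these values follow the spot median minus the mean of the blanks, times 1 factor per array. For miRNAs less than 30 above the blanks the Spearman correlation with the scan was 0.708 to 0.827, so the table's handling of dim spots stays unknown, while its linear scale and its direction (brighter is higher) were read from the comparison with the scan. In the control column 377 values carry more than 1 decimal, and none do in the other columns. The table lists 910 miRNAs for the control, 849 for TNFα, 942 for IL1α, 828 for IL1β and 902 for IL6.

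Spot medians were background-corrected with normexp (offset 50) on all spots, restricted to the miRNA probes and quantile normalized between arrays in limma 3.58.1 under R 4.3.3. Normalized intensities given below include the offset, so log2 ratios of dim miRNAs understate differences. A miRNA was called detected where its spot median lay more than 2 SDs above the mean of the array's blanks, after 5% of the blanks were dropped at each end. The trimmed blank mean was 30.1 for the control, 46.2 for TNFα, 28.4 for IL1α, 27.9 for IL1β and 28.4 for IL6. By this rule 701, 705, 800, 708 and 772 miRNAs were detected on the 5 arrays in that order, and 388 on all 5. On the TNFα array the 8 spots of 1 negative control probe averaged 54, against a detection limit of 53.5. The other negative control probes averaged 50 and 49.9 there, and on the other arrays all lay below the limit. Calls near the limit, above all with TNFα, can therefore include nonspecific signal. The detector gain was 47 for TNFα and 43 for the other arrays. The control and TNFα arrays were on slide 1, the IL1α and IL1β arrays on slide 2 and the IL6 array on slide 3. Of the comparisons with the control, that of TNFα lies within a slide, and for IL1α, IL1β and IL6 slide and treatment cannot be told apart. Spots flagged by the extraction software (2, both on the IL6 array) were left out. No value column of another sample was used (0 columns).

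Each cytokine array was compared with the control array as a log2 ratio over the miRNAs detected on both, counted at 2-fold, with no p-value, since each group holds 1 array. The number of arrays limits the precision, and no difference between 2 arrays has a replicate check. The 4 cytokine arrays were also fitted as 1 group against the control with limma (lmFit and eBayes with an intensity trend, two-sided, Benjamini-Hochberg threshold 0.05), over 1289 miRNAs detected on at least 1 array, with 3 residual degrees of freedom. In that fit the lone control array is assumed to vary like the cytokine arrays, whose spread also holds any difference between cytokines. On 20 simulated sets of 1289 miRNAs with 200 changed, the fit recovered 100% of changes of 1 and of 2 log2 units, with 8.75 false calls on average. The changes were added to normalized log2 values, after the offset, and the simulated spread was smooth in level as the fit assumes. The recovery therefore does not measure power for 2-fold changes of dim miRNAs, which the offset shrinks. The medians of 21 lists of miRNAs were set against 10000 random lists of the same size matched on mean level in 10 bins, and a median at or below the 2.5th or at or above the 97.5th percentile is called outside the random range. The lists were tested on values simulated at the spread of the 495 miRNAs of the TNFα comparison. Lists of 12 unchanged miRNAs lay outside that range in 6% of 200 cases, and lists shifted by 0.3 log2 units in 100% of 50. The simulated miRNAs varied independently, with 1 SD at every level. These rates therefore do not cover families whose members vary together, or lists with fewer measured members. Comparisons that share the control were set beside 1000 simulations of unchanged arrays, quantile normalized and counted in the same way.

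Named miRNAs were chosen by a rule. For each cytokine they are the 10 highest and 10 lowest log2 ratios among miRNAs detected on both arrays, with a mean level at or above the median of those detected on all 5, and with 1 sign under every normalization and background alternative. Added to these are the 5 highest and 5 lowest with 1 sign in all 4 comparisons, the 5 largest differences each way between IL1α and IL1β, the 10 brightest miRNAs, the 10 lowest p in limma and the members of the lists. The samples' groups, the tests, the lists, this rule and most alternatives were fixed before the data were examined. The alternatives were median scaling, 75th percentile scaling, cyclic loess, no normalization, blank subtraction (floor 1), a normexp offset of 16, no background correction, no filter on dim miRNAs, a filter at 10 SDs, the authors' values, spot means, a 1.5-fold threshold, limma without each cytokine array, eBayes without trend and agreement without TNFα. Blank subtraction with median scaling (also for bounds), ties counted as no common direction, the slide as a block and each other array as the lone array or shared reference were added after seeing the data. List medians were called moved where they differed from the main value by more than 1 SD of the random lists, and single log2 ratios where they differed by more than the robust SD of the pair. miRNA names are those of the array's design, 8 probes name several miRNAs, and no genome build is given in the sources used here, so no coordinates are printed. Other work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.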

Results

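Mature miRNA levels were measured in Caco-2 cells, a human colorectal adenocarcinoma line used as a model of the intestinal epithelium, left untreated or treated for 6 h with an inflammatory cytokine. By the labels the dose was 5 µM for TNFα and 10 µM for IL1α, IL1β and IL6. Each of the 5 conditions was represented by 1 array, so no difference between 2 arrays below has a replicate check. The comparisons ask which miRNAs differ between cytokine-treated and control cells at this time. The intestinal miR-192 and miR-194 had spot medians of 41 and 50 on the control array, against a detection limit of 34.6.

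With TNFα, the miR-29 family and several members of the miR-17 clusters were lower than in the control and a set of GC-rich miRNAs was higher. miR-29a, which targets extracellular matrix transcripts, had a normalized intensity of 83.3 on the TNFα array and 186 on the control array, a log2 ratio of -1.15. It was the 1 miRNA of 495 detected on both arrays that differed 2-fold. The count was also 1 with an offset of 16 and with no background correction, which likewise shrink the ratios of dim miRNAs. The count was 45 after blank subtraction, 54 with median scaling added and 30 in the authors' values, where miR-29a stood at -2.55. Its relatives miR-29b and miR-29c had log2 ratios of -0.65 and -0.28, and the family's median of -0.65 lay at the 0.06 percentile of random lists matched on level. miR-21, a miRNA induced in many inflamed tissues, had a log2 ratio of -0.49, and miR-19a, miR-106b and miR-27a had log2 ratios of -0.56, -0.46 and -0.46. miR-21, like miR-3960 below, is among the 10 brightest miRNAs, where quantile normalization sets values by rank in wide steps. The size of its ratio is therefore the gap between ranks, not a fold read from its own spots.

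Of the 12 measured members of the miR-17 cluster and its paralog clusters, which promote cell proliferation, 8 had a lower and 3 a higher value with TNFα. Their median log2 ratio was -0.28, at the 0.025 percentile of random lists. In the authors' values it was -0.94 with all 12 lower, and without normalization -0.04 with 7 lower and 5 higher. Random lists had medians of -0.666 and 0.115 in these 2 settings. miR-92a, encoded in the same cluster as miR-19a, had a log2 ratio of 0.31. In the miR-15/16 family 5 of 6 members had lower values, with a median of -0.23 at the 1.17 percentile, inside the random range under 5 of 12 alternatives, both forms of blank subtraction among them. miR-15a had a log2 ratio of -0.35 and miR-16 one of -0.25. The highest log2 ratios with TNFα among miRNAs detected on both arrays at or above the median level were 0.61 for miR-3960, 0.54 for miR-1973, 0.54 for miR-371-5p and 0.47 for miR-3651. In the list of GC-rich miRNAs with high array signal, fixed as a marker of hybridisation and RNA quality, 19 of 21 members were higher, with a median of 0.23 at the 99.995 percentile of random lists. In the authors' values this median was -0.11 and miR-3960 stood at -0.01, where the median of all miRNAs was -0.23. The same array had the higher detector gain and blanks given above, and its spike-in control spots were 2.41 and 2.07 times as bright above the blanks as those of the control array.

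**Figure D1:**
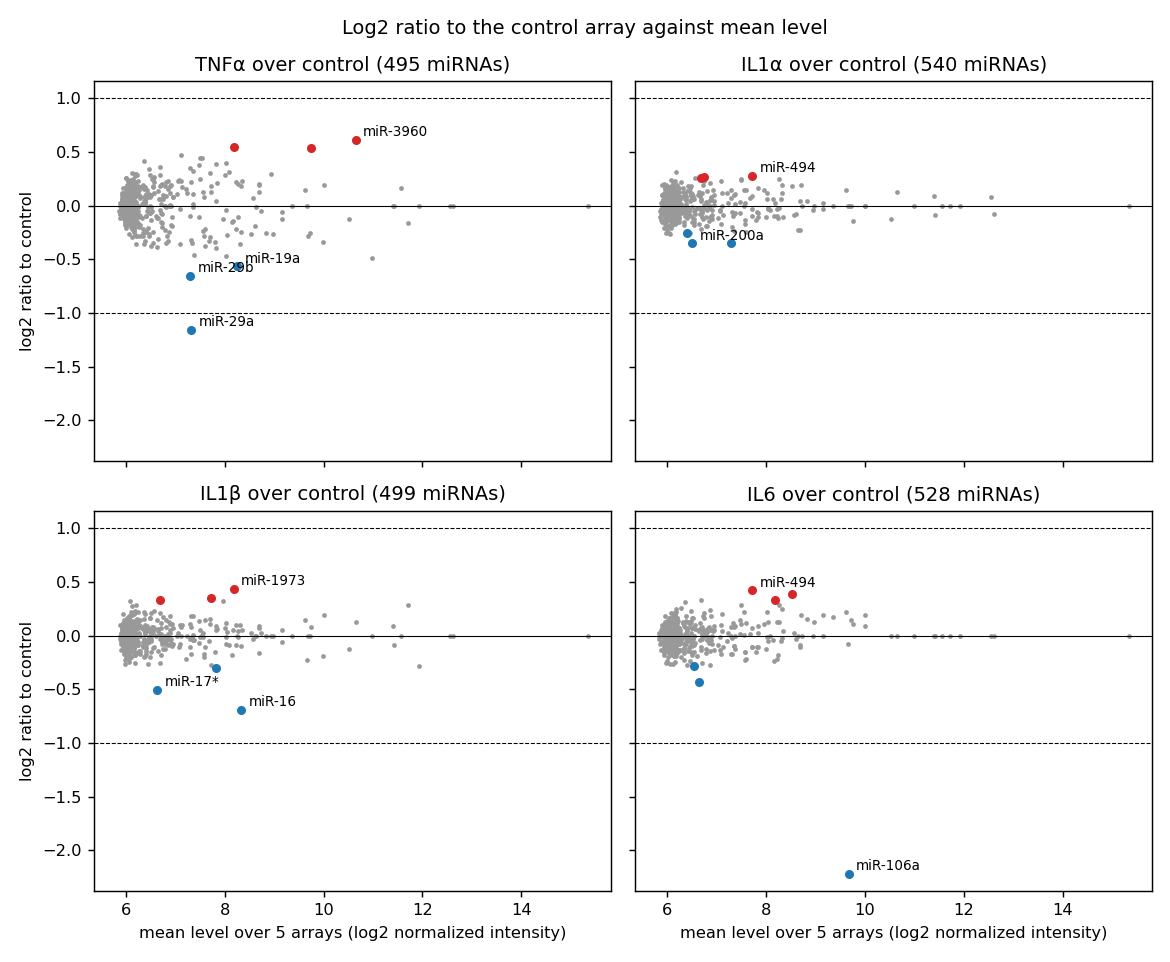
Log2 ratio of each cytokine array to the control array (vertical axis) against the mean log2 normalized intensity over the 5 arrays (horizontal axis), for the miRNAs detected on both arrays; each point is 1 miRNA, coloured points are the 3 highest (red) and 3 lowest (blue) by the naming rule, and dashed lines mark 2-fold. miR-29a at -1.15 with TNFα and miR-106a at -2.22 with IL6 are the points beyond 2-fold.

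With IL1α, no miRNA of 540 detected on both arrays differed 2-fold or 1.5-fold from the control. After blank subtraction 31 differed 2-fold and 103 differed 1.5-fold, and in the authors' values 15 and 77. Among miRNAs detected on both arrays at or above the median level, the lowest log2 ratios were -0.35 for miR-200a and -0.34 for miR-29b, and the highest were 0.28 for miR-494, 0.26 for miR-3135b, 0.26 for miR-4429 and 0.26 for miR-182. In the miR-200 family, which maintains the epithelial state by repressing ZEB factors, 3 of 4 measured members were lower, with a median of -0.18 at the 0.325 percentile. miR-200c and miR-200b had log2 ratios of -0.23 and -0.13 and miR-141 one of 0.14. The family's median lay inside the random range under 6 of the alternatives and was 0.00 after blank subtraction with median scaling, and from spot means miR-200c had a log2 ratio of 1.55. The miR-29 family had a median of -0.16, with all 3 members lower. The placental cluster of chromosome 19, with 8 members measured, had a median of 0.07 at the 97.7 percentile, and both of these lists lay inside the random range under several alternatives.

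With IL1β, miR-16, a repressor of cell cycle genes, was the 1 miRNA of 499 that differed 1.5-fold, with a log2 ratio of -0.69 and spot medians of 188 on the IL1β array and 330 on the control array. The pixels of that spot had a CV of 94.2%, against at most 26.8% on the other 4 arrays, and its family member miR-15b had a log2 ratio of -0.09. The mean of its pixels was 234, and from spot means no measured member of the miR-15/16 family was 1.5-fold lower with IL1β. Among miRNAs detected on both arrays at or above the median level, the next lowest were miR-17* at -0.50, miR-22 at -0.30 and miR-372, a miRNA of pluripotent cells, at -0.29. The highest were 0.43 for miR-1973, 0.35 for miR-494, 0.33 for miR-4429 and 0.33 for miR-24. No miRNA differed 2-fold. After blank subtraction 88 differed 1.5-fold and 24 differed 2-fold, and in the authors' values 68 and 14. The list of GC-rich miRNAs had a median of 0.07 at the 98.5 percentile and lay inside the random range under 8 of 12 alternatives.

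With IL6, miR-106a, a member of the X-linked paralog of the miR-17 cluster, had a normalized intensity of 249 against 1158 on the control array, a log2 ratio of -2.22. It was the 1 miRNA of 528 that differed 2-fold, against 27 after blank subtraction, 33 with median scaling added and 18 in the authors' values. Its spot median was 207 with IL6 and between 1026 and 1090 on the other 4 arrays. Its close relatives did not share this: log2 ratios with IL6 were -0.08 for miR-17, 0.22 for miR-20b and 0.07 for miR-18b. Among miRNAs detected on both arrays at or above the median level, the next lowest were miR-17* at -0.43 and miR-4521, miR-521 and miR-148a at -0.28. The highest were 0.42 for miR-494, 0.39 for miR-4723-5p, 0.34 for miR-1973 and 0.34 for miR-4429. Of the lists with at least 2 members measured, none lay outside the random range with IL6. The miR-30 family came nearest, with 4 of 5 members lower and a median of -0.13 at the 4.16 percentile, and lay outside after blank subtraction and with an offset of 16, as did the miR-15/16 family after both forms of blank subtraction.

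**Figure D2:**
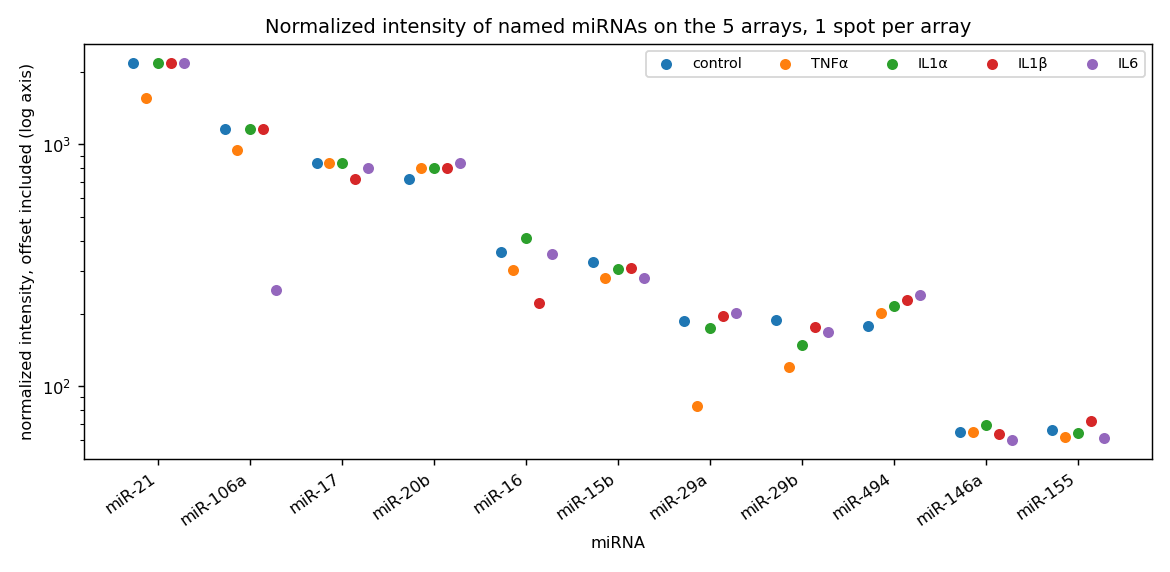
Normalized intensity (log axis, offset of 50 included) of 11 miRNAs on each of the 5 arrays, 1 spot per array and colour; no error bars are drawn because each condition has 1 array. miR-106a stands at 249 with IL6 and miR-29a at 83.3 with TNFα, while miR-146a and miR-155 lie near the lower end of the scale on every array.

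The NF-kB and inflammation-induced miRNAs that were detected on both arrays showed no common shift. Of the 28 on the list, any that rose from or fell to the level of the blanks were left out. With no filter on dim miRNAs no median lay outside the random range either, but the offset shrinks the ratios of dim members. An induction of such members can therefore be missed. Their median log2 ratio was -0.05 with TNFα, 0.01 with IL1α, 0.00 with IL1β and 0.01 with IL6, over 15 to 17 measured members, and each median lay between the 13.5 and 74.1 percentiles. miR-146a, a feedback regulator of NF-kB signalling, had spot medians of 37 on the control and 57, 37, 34 and 30 on the TNFα, IL1α, IL1β and IL6 arrays, against detection limits of 34.6, 53.5, 32.8, 32.5 and 32.9, so it was not detected with IL6. miR-155 had log2 ratios of -0.09, -0.03, 0.13 and -0.10 in the same order of cytokines. miR-21 had a log2 ratio of 0.00 with IL1α, IL1β and IL6, where its equal rank on the arrays gives equal values after quantile normalization. Differences in miR-146a and miR-155 that stay near the blanks were not detectable at this signal. On the TNFα array the miR-146a spot of 57 lay close to the mean of 54 (SD 5.8) of 1 negative control probe. Detection of miR-146a on that array is therefore uncertain. The IL6 and STAT3-linked list had medians of -0.09, 0.00, 0.01 and 0.00 and the tight junction and barrier-linked list medians of -0.07, -0.04, 0.00 and 0.04, all inside the random range.

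**Figure D3:**
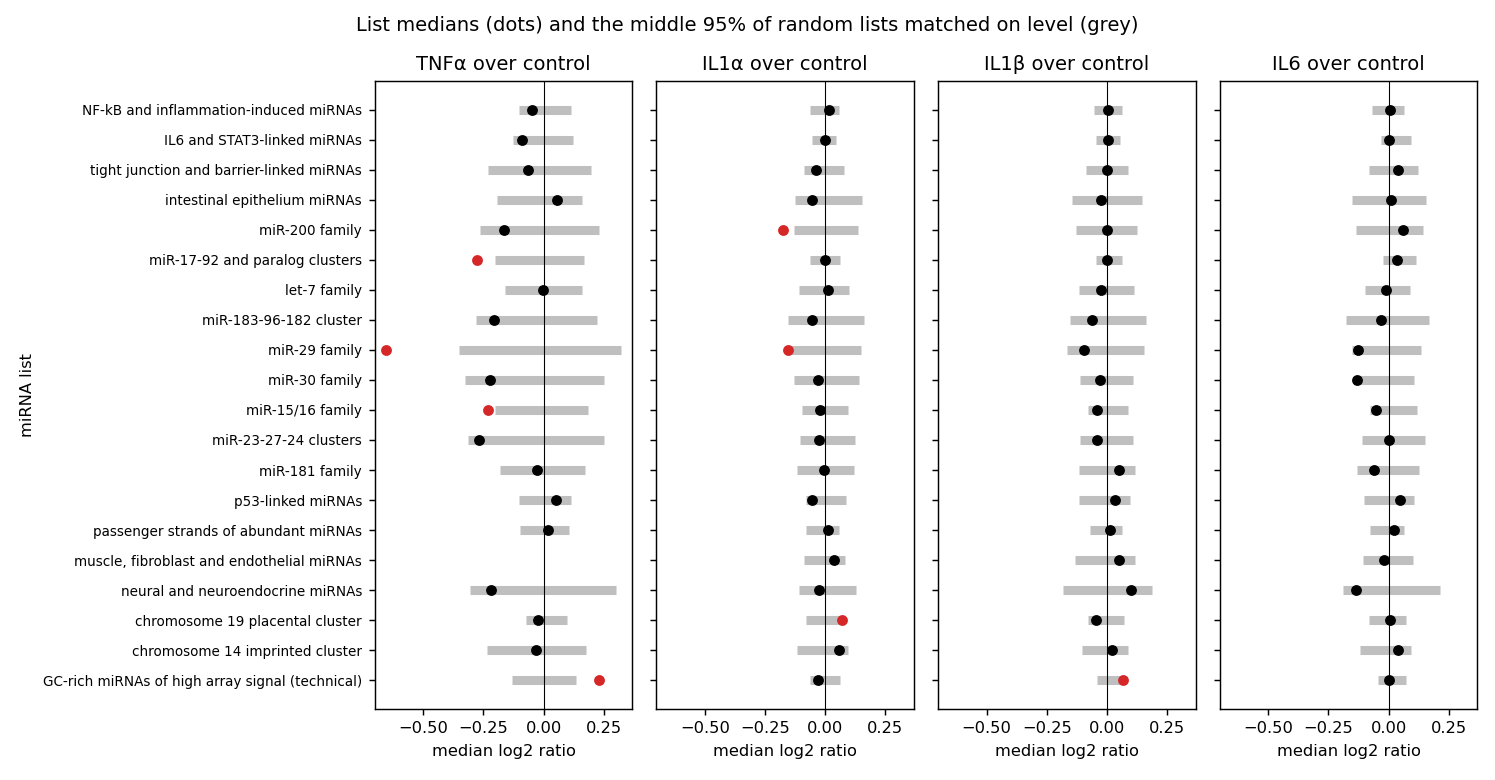
Median log2 ratio to control of each list of miRNAs (dots, horizontal axis) in the 4 comparisons, with the middle 95% of 10000 random lists matched on level (grey bars); red dots lie outside that range. Of 79 medians 8 are red, 4 of them with TNFα, where the miR-29 family is at -0.65 and the GC-rich list at 0.23.

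Over all lists, 8 of 79 medians lay outside the random range, 4 of them with TNFα, against 3.95 by chance. That number, like the one for IL1α over IL1β below, assumes that list members vary as independently as random miRNAs. Whether members of a family do so was not tested. The let-7 family had medians of 0.00, 0.01, -0.03 and -0.01 and the miR-181 family medians of -0.03, -0.01, 0.05 and -0.06 with TNFα, IL1α, IL1β and IL6. The miR-23-27-24 clusters stood at -0.27, the miR-30 family at -0.22 and the miR-183 cluster at -0.20 with TNFα, all 3 inside the range. Of the 8 blood and immune cell miRNAs 1 was measured in each comparison. At most 4 of the 10 muscle, fibroblast and endothelial miRNAs on the array and 3 of the 8 neural ones were measured. Over the whole array 495 to 540 of 1719 miRNA probes were measured, so low numbers were not particular to the muscle and neural lists. Their medians, with those of the intestinal, p53-linked, passenger strand and chromosome 14 lists, lay inside the range in each comparison where they could be computed.

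IL1α and IL1β signal through the same receptor, and their arrays shared a slide. No miRNA of 532 detected on both differed 2-fold between them, and 1, miR-16, differed 1.5-fold, with a log2 ratio of 0.88 for IL1α over IL1β that rests on the uneven spot named above. After blank subtraction 33 differed 2-fold and 115 differed 1.5-fold, and in the authors' values 19 and 87. miR-3135b and miR-17* were higher with IL1α, by log2 ratios of 0.39 and 0.33, and miR-1973 and miR-200a had log2 ratios of -0.41 and -0.35. In the authors' values miR-1973 stood at 0.01. The miR-200 family had a median log2 ratio of -0.16 for IL1α over IL1β, at the 1.61 percentile. It was 1 of 4 lists of 21 outside the random range for this pair, against 1.05 by chance, with the miR-29, neural and chromosome 19 lists. The robust SD of log2 ratios was 0.11 for this pair, 0.10 to 0.11 for the 6 pairs without TNFα and 0.16 to 0.19 for the 4 pairs with TNFα, whose typical spread was 1.62 times that of the others, or 1.12 times with no filter on dim miRNAs.

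For miRNAs detected on 1 array of a pair only a bound can be given. On the normalized scale none reached 1.5-fold in the comparisons with the control. Above the blanks with median scaling, bounds reached 2-fold for 63 miRNAs higher and 4 lower with TNFα, 31 and 18 with IL1α, 21 and 13 with IL1β and 26 and 22 with IL6. The split with TNFα is in part built in. Its detection limit was 53.5 over a blank mean of 46.2, against 34.6 over 30.1 for the control, with scaling medians of 28.3 and 23.9. On the scaled values the limit thus lay higher with TNFα, which raises bounds in that direction and lowers the others. Some miRNAs had the same direction in all 4 comparisons. miR-17*, the passenger strand of miR-17, had log2 ratios of -0.39 with TNFα, -0.17 with IL1α, -0.50 with IL1β and -0.43 with IL6, and miR-221, miR-30b and miR-29b were also lower on each cytokine array. miR-494 had log2 ratios of 0.18, 0.28, 0.35 and 0.42 and miR-4429 of 0.36, 0.26, 0.33 and 0.34. The authors' values put miR-494 at -0.07 with TNFα. Of 334 miRNAs with a nonzero ratio in each comparison, 38.6% had 1 direction in all 4, 64 higher and 65 lower. Unchanged arrays that share 1 control, normalized and counted the same way, gave 41.5% in simulation (36.5 to 47.2). Over all 388 miRNAs, with ties counted as no common direction, the share was 33.2% against a simulated 37.6%. The mean correlation across these 388, which are not independent replicates, was 0.35 against a simulated 0.50 (0.434 to 0.566). The mean covariance was 0.00733 against 0.0151 (0.012 to 0.019), so both lay below the simulated ranges. The simulated share was 41.5% with the control and with TNFα as reference, so the wider spread of pairs with TNFα was not simulated. Whether this mismatch lowers the observed values was not tested.

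Fitted together, the 4 cytokine arrays against the control gave 0 miRNAs at an adjusted p of 0.05 in limma, 51 at an unadjusted p of 0.05 against 64.5 by chance, and a lowest adjusted p of 0.139, for miR-106a. The unadjusted count was 11 to 32 with another or no normalization. With the slide as a block, the fitted difference is that of the TNFα array from the control array alone, because no other cytokine array shares the control's slide. That fit is therefore no test of the 4 cytokines together. Without each cytokine array in turn the lowest adjusted p in limma was 0.924 to 0.993. With a normexp offset of 16 or no background correction miR-106a passed the threshold, with fitted log2 ratios of -0.67 and -0.65. These rest mainly on its spot on the IL6 array, which lay below the mean of the other arrays, control included, by 2.14 log2 units. They are therefore no evidence of an effect common to the 4 cytokines. Other miRNAs passed the threshold with spot means. miR-17* had a log2 ratio of -0.37 (SE 0.14) and a limma adjusted p of 0.990.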

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

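The tests of the TNFα array below were chosen after its values had been seen. The 2 kinds of spike-in control spots, which no comparison above uses, were brighter on the TNFα array than on the control array by more than 2 SDs of their spots. Above the blanks the ratio was 2.41 for the first kind and 2.07 for the second, each over 8 spots, while on the IL1α, IL1β and IL6 arrays it lay between 0.86 and 1.03.

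On that array the GC-rich list lay above the control and the miR-17 cluster, miR-29 and miR-15/16 lists below it. The higher detector gain alone would raise the miRNAs with the spikes, but the 388 miRNAs detected on all arrays had a median ratio above the blanks of 1.34. Less labelled RNA alone would lower all miRNAs by 1 factor. The GC-rich list had a median ratio above the blanks of 1.60, against 1.19 for 192 other bright miRNAs. Its median log2 ratio of 0.23, itself part of the pattern, lay outside the random range in the main setting and after blank subtraction. The IL1β array, at the same position on its slide, had its GC-rich list at the 98.5 percentile, but with a median of 0.07 and inside the range under 8 of 12 alternatives and outside it under 4, so a position effect stays open for part of the shift. A hybridisation or RNA quality difference and a response to TNFα cannot be told apart, because the treatment has 1 array.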

How the results depend on the processing

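The alternatives with median scaling after blank subtraction, with a lone array other than the control, with the slide as a block and with ties counted were chosen after seeing the data; the cause of the moves below was not tested unless named. The count of 2-fold differences was 1 for TNFα, 0 for IL1α, 0 for IL1β, 1 for IL6 and 0 between IL1α and IL1β. It was 45, 31, 24, 27 and 33 after blank subtraction, 54, 31, 22, 33 and 31 with median scaling added, 30, 15, 14, 18 and 19 in the authors' values, and 3, 4, 4, 3 and 3 with spot means. It stayed 1, 0, 0, 1 and 0 with an offset of 16 and with no background correction. Like the main setting, these leave an added amount in each value, which shrinks the ratios of dim miRNAs. Their equal counts are therefore no separate check of the low main counts. By direction, blank subtraction gave 18 higher and 27 lower for TNFα, and 44 and 10 with median scaling added; the authors' values gave 5 and 25. At 1.5-fold the counts were 3, 0, 1, 1 and 1. For TNFα the count was 0 without normalization and 0 with the filter at 10 SDs. The median of all miRNAs moved with TNFα by 0.19 without normalization and by 0.21 with median scaling added, and stood at -0.23 in the authors' values, which also put IL1β at -0.15.

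The limma count of 0 became 1 with a normexp offset of 16, 1 without background correction and 5 with spot means. It stayed 0 without each cytokine array in turn and without trend. The fit with the slide as a block (1 residual degree of freedom) compares the TNFα array with the control array alone, which shared a slide. It is therefore no form of the fit of 4 cytokines. The unadjusted count of 51, against 64.5 by chance, was 11 without normalization and 26 to 32 with other normalizations. With a lone array of TNFα, IL1α, IL1β or IL6 the adjusted count was 9, 2, 2 and 1 and the unadjusted count 172, 34, 51 and 28. The adjusted calls include miR-21 for TNFα and miR-373 for IL1α, whose equal ranks on the other 4 arrays leave a spread of 0. The spread of pairs with TNFα was 1.62 times that of the others, 1.12 times with no filter on dim miRNAs and 2.08 times at 10 SDs. The share with 1 direction in all 4 was 38.6%, then 33.2% with ties counted as no common direction, 31.4% with the filter at 10 SDs, and 52.8% over 3 comparisons without TNFα, where fewer comparisons raise it by construction.

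The number of comparisons in which a list lay outside the random range moved as follows. GC-rich: 2, and 1 under median, 75th percentile, cyclic loess and no normalization, blank subtraction with and without median scaling, no background correction and spot means. miR-29: 2, and 1 under blank subtraction, no background correction and spot means. miR-200: 1, and 0 under median, 75th percentile and no normalization, spot means, blank subtraction with median scaling and 10 SDs. miR-15/16: 1, and 0 under offset 16, spot means and 10 SDs; under blank subtraction with and without median scaling its 1 was IL6 in place of TNFα. Chromosome 19: 1, then 2 under blank subtraction with and without median scaling, and 0 under offset 16, no background correction, authors' values and no filter. At 10 SDs the miR-29, chromosome 19 and 9 other lists could not be computed in each comparison, and in the authors' values 1 list. Lists at 0 reached 1 as follows: IL6 and STAT3-linked and chromosome 14 without a filter, intestinal and p53-linked with spot means, miR-30 under blank subtraction and offset 16, miR-23-27-24 at 10 SDs, and passenger strands under blank subtraction with and without median scaling, no background correction and authors' values. The GC-rich median changed sign in the authors' values, to -0.11 with TNFα and -0.0764 with IL1β, and the miR-200 median with IL1α was 0.0015 after blank subtraction with median scaling.

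Of the alternatives for named log2 ratios, 778 moved by less than the pair's robust SD and 342 by more. Of these, 12 changed sign, 10 of them in the authors' values and the rest with spot means or blank subtraction with median scaling. These settings were not part of the naming rule. miRNAs named for high or low ratios had been chosen for a constant sign under the other normalization and background alternatives. The lack of sign changes there follows from that choice and does not measure how stable the directions are. At 10 SDs the values are few: 169 to 206 of 1719 miRNAs passed the filter at 10 SDs.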

Other observations

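The tests of single spots below were chosen after the values had been seen, and the noise simulation was set out beforehand. miR-371-5p, of an embryonic cluster, read 797 on the control array and 1158 with TNFα, a log2 ratio of 0.54, against -0.15 with IL1α, 0.08 with IL1β and 0.10 with IL6. In the authors' values it stood at 0.25 with TNFα. miR-373 and miR-372, of the same cluster, had equal ranks on the TNFα and control arrays and so a log2 ratio of 0.00, but -0.33 and -0.36 after blank subtraction with median scaling and -0.79 and -0.86 in the authors' values.

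Low on 1 array alone were miR-106a with IL6, miR-29a with TNFα and miR-16 with IL1β, whose spot had a pixel CV of 94.2%, above all 68 spots of like brightness on its array, so an uneven spot is a candidate explanation of its low value. The miR-106a spot had a CV of 24.3%, at the 46.2 percentile of like spots and within the 9.70 to 30.5% of its other arrays, which argues against an uneven spot there. The miR-29a spot had a CV of 45.3%, at the 42.8 percentile of like spots but above the 23.3 to 29.8% of its other arrays, so an uneven spot stays open. A loss of the transcript that miR-106a shares with miR-20b and miR-18b would lower all 3, and the lower of the other two log2 ratios was 0.0734. Whether the probes of miR-20b and miR-18b also bind their close relatives in the miR-17 cluster was not tested, so these values cannot exclude such a loss. A loss of that transcript, an evenly dim spot or a change in mature miR-106a alone stays open, as does a lower miR-29a.

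After blank subtraction with median scaling, 54, 31, 22 and 33 miRNAs differed 2-fold with TNFα, IL1α, IL1β and IL6. Unchanged miRNAs with the noise of the blanks gave a median of 12, 9, 9 and 9 in 1000 simulations, at the lowest 22.2% of the observed count. This went against the blanks' noise as the whole source by the bound set beforehand, but that bound was wrong for this design: a simulation of blanks holds no variation between single arrays in printing, labelling or hybridisation. Whether the remainder is such variation or a response stays open with 1 array per condition.

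With the TNFα array as the shared reference, 65.5% of the miRNAs without ties had 1 direction in all 4 ratios, against 41.5% in simulations of unchanged arrays (36.6 to 46.6). The share was 38.6% with the control, 35.2% with IL1α, 32.8% with IL1β and 39.4% with IL6, where the simulated medians were 41.5 to 41.8%. The IL1α and IL1β shares lay below the simulated ranges, and the control and IL6 shares inside them. The near equal simulated medians show that the wider spread of pairs with TNFα was not simulated. Whether it accounts for the shares outside the ranges was not tested.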
